A study of Mus musculus with 10 samples.

How the data were processed

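Samples were lumbar spinal cord of mice given paclitaxel (5 libraries) or vehicle (5 libraries). Per the labels' protocols, RNA was extracted with silica columns, and mRNA libraries made from it were sequenced on an Illumina instrument. The deposited table holds RSEM expected counts per gene for each library, not scaled to depth. Per the submitters' processing notes, STAR, RSEM and edgeR 4.2.0 were used with genome build mm10. The versions of STAR and RSEM, the annotation release, the strand setting and any read filter are not given in the sources used here. Expected counts divide reads that fit several genes by a model, so genes with near-identical copies (Hspa1a and Hspa1b, ribosomal protein genes, protocadherin genes) carry more error than their counts show. Of the values, 5.04% were not whole, and all were rounded to whole numbers before testing.

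The library totals reported below were summed from the expected counts before rounding. No library pair within a group agreed within sampling noise (chi-square per degree of freedom from 1.61 to 6.89), so each library counted as a replicate. Counts were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3) at its defaults, a minimum count of 10 and a minimum total of 15. Libraries were scaled with TMM factors. The comparison was fitted without covariates by the quasi-likelihood test with robust dispersions, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, two-sided. CPM values use the TMM-scaled library sizes, and log2 CPM adds a prior count of 2. Standard errors were computed from the fold change and its F statistic, and intervals are at 95%. The common biological coefficient of variation was 8.23%. Exact permutation tests of single values ran over all 252 assignments of the libraries.

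The choice of test, filter, gene lists, named genes and alternatives was made before the data were examined, except where stated. Named genes were Calcrl, Kmt2d and Kmt2b, then up to 10 genes per direction. These were to be those with the largest change among genes that passed, with a mean of at least 1 CPM, a proper gene symbol and all 5 paclitaxel libraries on the same side of the vehicle mean, and where too few passed, the genes of lowest p filled the places. Of each list described gene by gene, up to 4 members of lowest p were named. Which lists to describe so was chosen after the list results were seen. Ramp1, Ramp3, Hspa1a, Hspa1b, Ddx3y and 6 glucocorticoid response genes (Plin4, Sgk1, Zbtb16, Cdkn1a, Hif3a and Sult1a1) were named after their values were seen.

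The 41 gene lists were pathways linked to pain and to paclitaxel, cell types of the cord, tissue that dissection can add, and library quality. The 37 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), again with an estimated correlation, and with fry. A list score is the mean over members of log2 CPM minus the vehicle mean. On 10 sets of simulated counts with the real means, dispersions and library sizes, for this comparison and 13183 to 13211 genes, edgeR recovered 19.3% of genes changed 1.2-fold, 73.6% of those changed 1.5-fold and 91.8% of those changed 2-fold. In each set 200 genes were changed, and the rates need not hold where fewer are. False calls made up 6.69% of all calls, and 5 genes were called over 10 further sets in which nothing was changed. The smallest simulated change and the number of sets were altered after first runs on a single set, in which false calls made up a larger share. In a single simulated set, camera with the preset correlation called the heat shock list, lowered there by 0.2 on the log2 scale, with 0 other lists called. Simulated genes were drawn independently of each other, so this cannot show how often camera calls lists of correlated genes. The real heat shock list had an estimated correlation of 0.34.

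Alternatives were DESeq2 size factors, upper-quartile scaling or library totals in place of TMM, no filter on low counts, a filter of at least 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, edgeR's likelihood ratio and exact tests, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and leaving out each library in turn. Added after the data were seen were leaving out paclitaxel replicate 3 and vehicle replicate 4 together, a loess correction for GC content and transcript length, thinning to the smallest library, and the heat shock list without Hspa1a and Hspa1b. GC content and length came from GENCODE release M21 transcripts for 99.7% of tested genes. Coordinates are those of RefSeq genes on GRCm38, the assembly that mm10 names.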

Results

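RNA from the lumbar spinal cord of mice was sequenced after treatment with paclitaxel or with vehicle. Paclitaxel is a microtubule-stabilising cancer drug whose dose-limiting side effect is a painful peripheral neuropathy. The lumbar cord receives the sensory input of the hind limbs. Each group held 5 libraries, named here by group and replicate number. Total gene counts ran from 3676259 to 5432072 in the paclitaxel libraries (mean 4705365 ± 752260, SD, n = 5) and from 4585899 to 7791594 in the vehicle libraries (mean 5657619 ± 1302660, SD, n = 5). The totals did not differ beyond the spread between libraries (exact permutation test, two-sided, p = 0.167). At this depth 3 counts corresponded to between 0.385 and 0.819 CPM, the count scaled to the library total. Counts were present for 18535 of 24411 listed genes, and 13287 genes were tested. The labels do not say whether the 5 samples of a group were separate animals, so p-values measure only the spread between these samples.

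The study is about the neuropeptide receptor gene Calcrl and the histone methyltransferase MLL2 in the spinal cord after paclitaxel. Calcrl encodes the receptor that binds calcitonin gene-related peptide (CGRP) together with Ramp1 and adrenomedullin together with Ramp2 or Ramp3. Calcrl lies on chromosome 2 from 84330626 to 84425405 (GRCm38). Its level was 16.0 ± 2.20 CPM with paclitaxel and 11.5 ± 2.46 CPM with vehicle (SD, n = 5 each), a 1.38-fold ratio with a 95% interval from 1.13 to 1.69. All 5 paclitaxel libraries lay above the vehicle mean, at 13.4, 14.4, 18.3, 15.8 and 18.2 CPM, and the highest vehicle library, replicate 1, reached 15.4 CPM. The log2 fold change was 0.46 (SE 0.14). Taken alone the difference exceeded the spread between libraries (exact permutation test, two-sided, p = 0.0238, where the smallest possible value is 0.00794), which is not independent evidence because the study is about this gene in these samples. Across all genes it did not pass the threshold (edgeR quasi-likelihood test, unadjusted p = 0.00317, adjusted p = 0.792), and it ranked 47 by p. After a correction for GC content and transcript length, added after the data were seen, the log2 fold change was 0.36.

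MLL2 has been used as a name for both Kmt2d and Kmt2b, which encode methyltransferases of lysine 4 of histone H3, so both were read out. Kmt2d, on chromosome 15 from 98831669 to 98874077, was at 170 ± 22.5 CPM with paclitaxel and 171 ± 22.3 CPM with vehicle (SD, n = 5 each). Its log2 fold change was -0.004 (SE 0.10, 95% interval -0.23 to 0.22; edgeR adjusted p = 0.997). Kmt2b, on chromosome 7 from 30568855 to 30589056, was at 78.4 ± 3.73 and 79.0 ± 3.41 CPM (SD, n = 5 each). Its log2 fold change was -0.012 (SE 0.06, 95% interval -0.14 to 0.12; edgeR adjusted p = 0.987). These intervals exclude an increase in mRNA above 1.17-fold for Kmt2d and above 1.09-fold for Kmt2b. Among the 18 members of the H3K4 methyltransferase complexes, 8 were higher and 10 lower, and the lowest p belonged to Cxxc1, the CpG-binding subunit of the SET1 complexes, with a log2 fold change of -0.26. Men1 (-0.15, and -0.10 without paclitaxel replicate 3), Pagr1a (-0.16) and Rbbp5 (0.14) followed. No member passed, over all genes or adjusted over the list alone.

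The genes of CGRP itself were lower in value. Calca and Calcb encode the α and β forms of CGRP, which motor neurons of the cord also express. Calca was at 22.3 ± 4.52 CPM with paclitaxel and 30.5 ± 7.14 CPM with vehicle, and Calcb at 8.04 ± 2.15 and 10.7 ± 1.91 CPM (SD, n = 5 each). Their log2 fold changes were -0.42 (SE 0.19) and -0.39 (SE 0.18), with 5 of 5 paclitaxel libraries below the vehicle mean for each gene, and neither passed (edgeR adjusted p = 0.80 and 0.79). Without paclitaxel replicate 3 that of Calcb was -0.23. The co-receptor Ramp2 differed by 0.11, Ramp1 by 0.05 and Ramp3 by 0.05 on the log2 scale, all within their standard errors. With each library left out in turn, Ramp2 ran from -0.01 to 0.17, Ramp1 from 0.02 to 0.09 and Ramp3 from -0.09 to 0.29. Over the 8 tested genes of CGRP and adrenomedullin signalling, the median log2 fold change was 0.03 with a mean of -0.016 (camera adjusted p = 0.935). No gene of this list passed over all genes. Adjusted over the list alone, 1 gene passed, Calcrl (adjusted p = 0.0253), with the same limit.

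**Figure D1:**
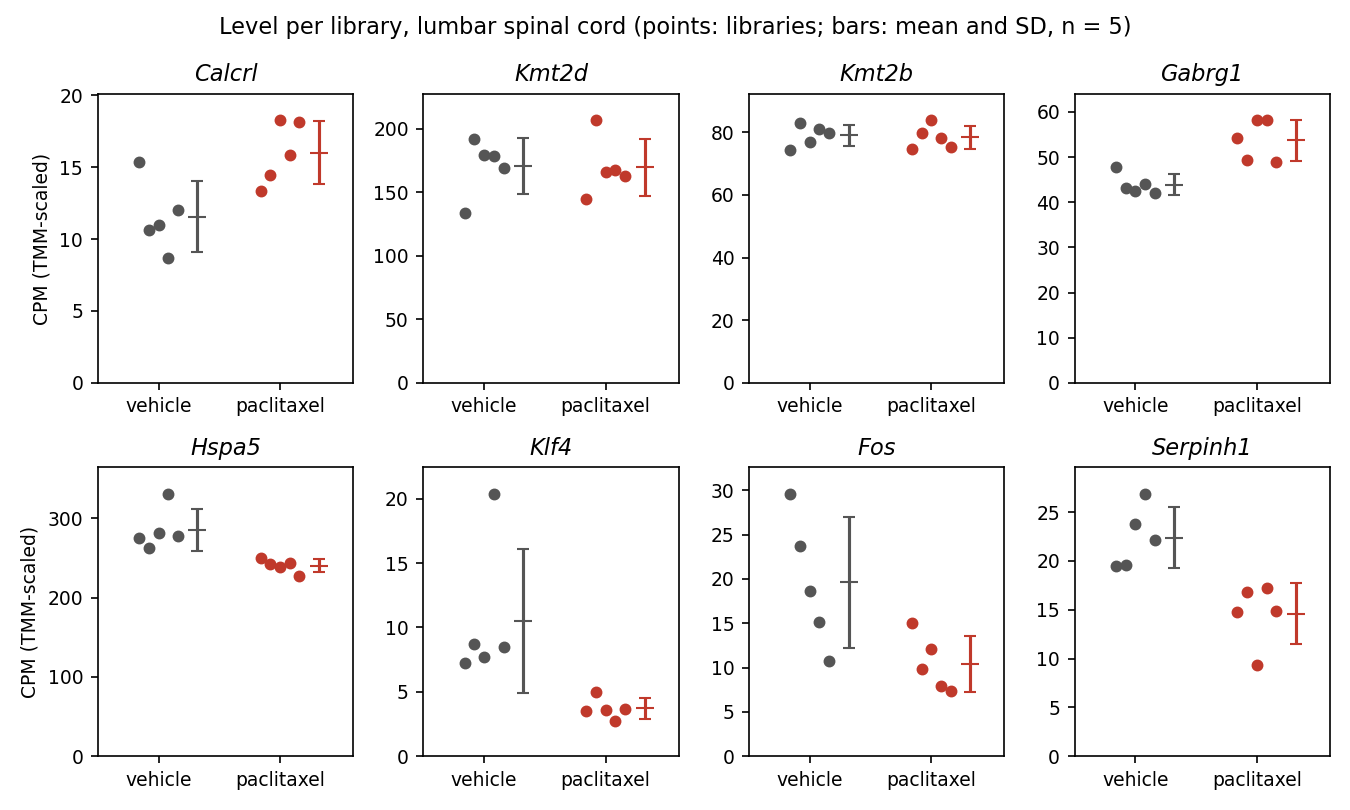
Level of 8 genes in CPM (vertical axes, each from 0) in the 5 vehicle and 5 paclitaxel libraries; points are libraries and bars the mean and SD. The paclitaxel libraries lie above the vehicle mean for Calcrl and Gabrg1 and below it for Hspa5, Klf4, Fos and Serpinh1, while the means of Kmt2d (170 and 171 CPM) and Kmt2b (78.4 and 79.0 CPM) nearly coincide; no gene passed edgeR's quasi-likelihood test over all genes.

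Whole-transcriptome comparison of paclitaxel with vehicle gave small differences. The median absolute log2 fold change was 0.08, and 0 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test (0 higher, 0 lower; smallest adjusted p = 0.792). At an unadjusted p under 0.05 there were 806 genes, 391 higher and 415 lower, where 664 would be reached by chance. The count was 515 without vehicle replicate 3, 1299 without vehicle replicate 1 and 596 after the correction for GC content and length. DESeq2 called 1 gene and edgeR's likelihood ratio test 1 gene, Klf4 in both cases, edgeR's exact test called 2, Klf4 and Nes, and limma-voom called 0 with and without sample quality weights. The groups did not overlap in 1.09% of tested genes, where chance gives 0.794%.

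Among genes with a proper symbol that were higher with paclitaxel, the 10 of lowest p did not pass in edgeR (adjusted p = 0.792 for each). Gabrg1, the γ1 subunit of the GABA-A receptor, was at 53.7 ± 4.54 CPM with paclitaxel and 43.9 ± 2.28 CPM with vehicle (SD, n = 5 each; log2 fold change 0.29, SE 0.08). Tafa1 (listed as Fam19a1), a secreted chemokine-like protein of the brain, had a log2 fold change of 0.51 (SE 0.14), and Nln, the neurotensin-cleaving peptidase neurolysin, of 0.34 (SE 0.10). Tbl1xr1, a subunit of the NCoR corepressor complex, had a log2 fold change of 0.31, and Erbin (listed as Erbb2ip), a scaffold of the receptor ERBB2, of 0.26. The others were Ccnyl1 (0.40), the P5-type ATPase gene Atp13a4 (0.35), Vma21 (0.27), needed to assemble the vacuolar proton pump, and the actin-severing factor Cfl2 (0.19). Rpl30, at 0.61, is uncertain because ribosomal protein genes have many near-identical processed pseudogenes.

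Among those lower with paclitaxel, the 10 of lowest p did not pass in edgeR's quasi-likelihood test either (adjusted p = 0.792 for each). Serpinh1, the collagen chaperone HSP47, had the lowest p of all genes, at 14.6 ± 3.14 CPM with paclitaxel and 22.4 ± 3.10 CPM with vehicle (SD, n = 5 each; log2 fold change -0.61, SE 0.14). Hspa5, the chaperone BiP of the endoplasmic reticulum, was at 240 ± 8.04 and 285 ± 26.5 CPM (SD, n = 5 each; -0.25, SE 0.06). Klf4, an immediate early transcription factor, was at 3.70 ± 0.81 and 10.5 ± 5.56 CPM (SD, n = 5 each; -1.44, SE 0.32), and vehicle replicate 4 alone held 20.4 CPM. The cytosolic cochaperones Dnajb1 and Ahsa1 had log2 fold changes of -0.28 (SE 0.07) and -0.22 (SE 0.06). The others were the mRNA export factor Alyref (-0.38), the endophilin gene Sh3gl1 (-0.36), the retinoid X receptor gene Rxrb (-0.26), the very large interferon-inducible GTPase gene Gvin1 (-1.28, from 1.12 and 2.71 CPM) and Pcdhgb7 (-0.37). Pcdhgb7 is uncertain because the protocadherin γ genes share their 3′ exons, and Gvin1 because it has close relatives in the same family. These 20 genes were picked only from genes with all 5 paclitaxel libraries on the same side of the vehicle mean, so that trait is not a result.

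Of 37 gene lists tested with camera, 5 passed an adjusted p of 0.05 with the preset correlation, 4 lower and 1 higher with paclitaxel. None of the 5 held with a correlation estimated from the data (0 of 37 lists, 2 at an unadjusted p under 0.05), and fry called 0 lists as moving on balance one way and 0 as changing in either direction. The number of lists called with the preset correlation was 9 without paclitaxel replicate 3 or 4, 8 without paclitaxel replicate 5 and 3 without vehicle replicate 2.

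The heat shock list, cytosolic chaperones and their regulators, was lower with paclitaxel, with 15 of 17 members lower and a median log2 fold change of -0.12 (camera adjusted p = 9.44e-09; adjusted p = 0.501 with an estimated correlation). The list score was below the vehicle mean in all 5 paclitaxel libraries (-0.44 to -0.14). Every vehicle library except replicate 4 (0.27) was also below that mean (-0.15 to -0.03), and the groups overlapped. No member passed over all genes, and 3 passed adjusted over the list alone: Dnajb1, Ahsa1 and Hsf1, the master transcription factor of the response (27.8 ± 3.29 CPM with vehicle and 21.7 ± 1.64 CPM with paclitaxel, SD, n = 5 each; log2 fold change -0.34, SE 0.10). The abundant chaperone Hsp90ab1 had a log2 fold change of -0.12, and of -0.08 without paclitaxel replicate 3. The inducible Hspa1a and Hspa1b had log2 fold changes of -0.86 (SE 0.33) and -1.88 (SE 0.74), which are uncertain because the pair is near-identical in sequence and because they fall to -0.53 and -0.98 without vehicle replicate 4. Vehicle replicate 4 held 44.3 CPM of Hspa1a and 54.9 CPM of Hspa1b, against at most 22.2 and 12.1 CPM in the other vehicle libraries. The same library had a score of 0.90 for genes of the meninges and fibroblasts, against -0.06 or lower in the other vehicle libraries. Without it the heat shock list had a median of -0.10 (camera adjusted p = 3.52e-08), and without both it and paclitaxel replicate 3 of -0.07 (4.76e-06), with adjusted p from 1.57e-12 to 0.501 over all settings. Fry did not call the list (adjusted p = 0.469).

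Immediate early genes, which neurons and glia switch on within minutes of stimulation, were lower as a list, with 18 of 21 members lower and a median of -0.19 (camera adjusted p = 0.0018; adjusted p = 0.501 with an estimated correlation). In edgeR's quasi-likelihood test without a block no member passed over all genes, and 1, Klf4, passed adjusted over the list alone. Klf4 passed over all genes in DESeq2 (adjusted p = 0.0191) and in edgeR's likelihood ratio (0.031) and exact tests (0.00152). Fos was at 10.4 ± 3.16 CPM with paclitaxel and 19.6 ± 7.36 CPM with vehicle (SD, n = 5 each; log2 fold change -0.90, SE 0.31; edgeR adjusted p = 0.792). With the replicate number as a block Fos passed over all genes (adjusted p = 0.0189), although the labels do not say that the numbers pair the samples. Klf2 had a log2 fold change of -0.63 (-0.39 without vehicle replicate 4) and Dusp6 of -0.23 (-0.14 without paclitaxel replicate 3 or vehicle replicate 1). The median was -0.10 without vehicle replicate 1 (camera adjusted p = 0.0233) and -0.13 without vehicle replicate 4 (9.18e-04), with adjusted p from 2.10e-06 to 0.501 over all settings.

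The unfolded protein response list was lower, with 15 of 21 members lower and a median of -0.08 (camera adjusted p = 0.00665; adjusted p = 0.688 with an estimated correlation). No member passed over all genes, and 1, Hspa5, passed adjusted over the list alone. The protein disulfide isomerases Pdia4 (-0.21) and Pdia6 (-0.19, and -0.11 without vehicle replicate 4) and the secreted factor Creld2 (-0.30) had the next lowest p. The call ended without vehicle replicate 4 (median -0.05, camera adjusted p = 0.0756) and without both that library and paclitaxel replicate 3 (-0.03, 0.158). Without paclitaxel replicate 3 alone the list was still called, at a median of -0.034 (0.0219), with adjusted p from 4.88e-04 to 0.688 over all settings.

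Sterol synthesis genes were lower, with 17 of 20 members lower and a median of -0.06 (camera adjusted p = 0.0189; adjusted p = 0.903 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The mevalonate pathway genes Pmvk (-0.24), Fdps (-0.16) and Mvd (-0.28) and the regulator Srebf2 (-0.10) had the lowest p. Without paclitaxel replicate 3 Fdps was at -0.07, Srebf2 at -0.05 and Mvd at -0.19, while Mvd was at -0.44 without paclitaxel replicate 2. Paclitaxel replicate 3 had the lowest score of this list, -0.40, and in the same library the list of glucocorticoid response genes stood at 1.32. The median was -0.11 without paclitaxel replicate 1 or 2 and -0.09 without vehicle replicate 5. The sterol call ended without paclitaxel replicate 3 (median 0.005, camera adjusted p = 0.912), without vehicle replicate 1 (0.003, 0.586) and without vehicle replicate 2 (-0.03, 0.103). It also ended in limma-voom with sample quality weights (-0.01, 0.381) and with 1 surrogate variable (0.007, 0.845), which mostly marked paclitaxel replicate 3. Without both paclitaxel replicate 3 and vehicle replicate 4 it ended too (-0.03, 0.278), with adjusted p from 3.26e-04 to 0.912 over all settings.

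Receptors for GABA and glycine with chloride transporters, the machinery of fast inhibition in the dorsal horn, were higher as a list, with 15 of 20 members higher and a median of 0.06 (camera adjusted p = 0.0308; adjusted p = 0.841 with an estimated correlation). No member passed over all genes, and 1, Gabrg1, passed adjusted over the list alone. Gabra3 (0.16) and Gabra4 (0.19) were also among the members of low p. The call ended without paclitaxel replicate 1 (median 0.03, adjusted p = 0.118) or 3 (0.04, 0.058), without vehicle replicate 3 (0.01, 0.238) or 5 (0.04, 0.09), in limma-voom with sample quality weights (0.04, 0.0606) and, at a median still of 0.06, without vehicle replicate 2 (0.0773). Without vehicle replicate 1 the median was 0.10 (0.0149). It also ended after the correction for GC content and length (median 0.01, camera adjusted p = 0.574), with a range from 0.0149 to 0.841 over all settings.

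**Figure D2:**
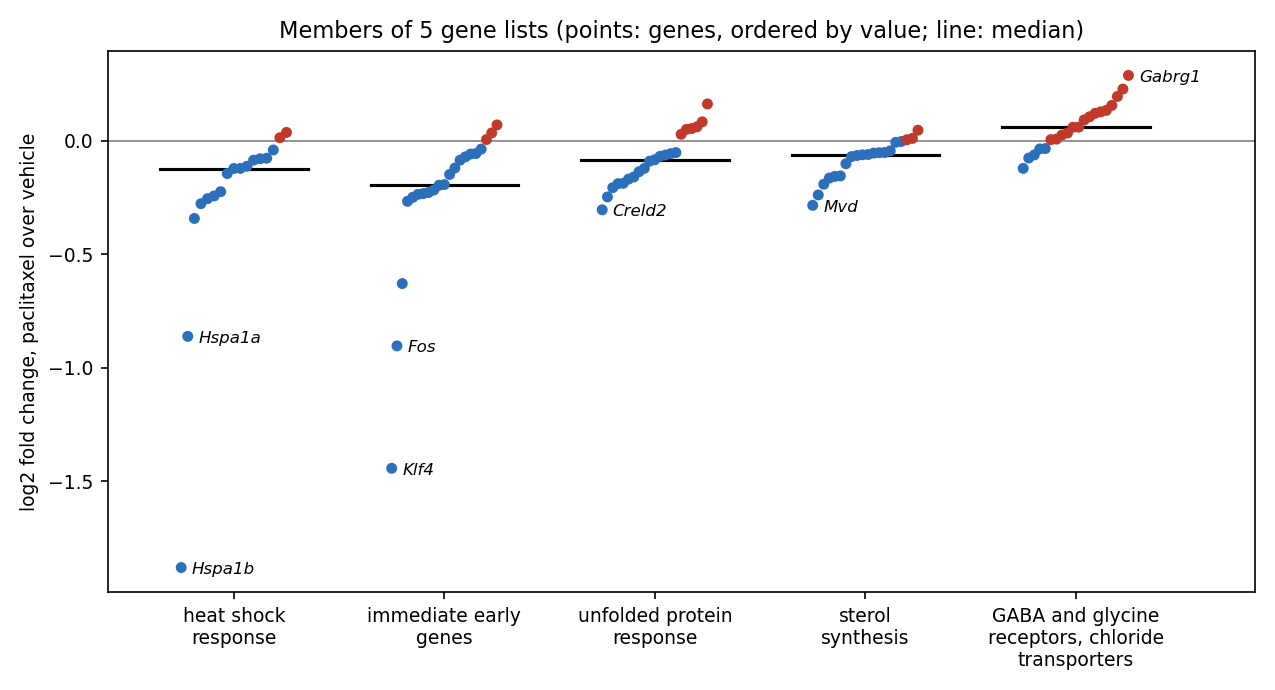
Log2 fold change of paclitaxel over vehicle (vertical axis) for each tested member of the 5 gene lists that passed camera with the preset correlation; points are genes ordered by value, black lines the list medians. Medians run from -0.19 for immediate early genes to 0.06 for GABA and glycine receptors, and Hspa1b (-1.88), Klf4 (-1.44), Fos (-0.90) and Hspa1a (-0.86) lie farthest from 0, with Hspa1b at -0.98 without vehicle replicate 4; no call held with an estimated correlation.

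Other gene groups tied to pain did not pass. Ion channels linked to pain had a median of 0.01 (camera adjusted p = 0.627), with Cacna1e, a calcium channel subunit, at 0.25 (SE 0.08), the sodium channel genes Scn9a and Scn3a at 0.40 (SE 0.15) and 0.31 (SE 0.12), and Trpm2 at -0.15. Scn3a was at 0.20 without paclitaxel replicate 3. Genes of inhibitory dorsal horn neurons had a median of -0.07 (adjusted p = 0.63), with 5 members higher and 6 lower. That median ran from -0.11 to 0.04 when each library was left out. In that list 1 gene passed adjusted over the list alone, the vesicular GABA and glycine transporter Slc32a1 (248 ± 22.6 CPM with paclitaxel and 284 ± 16.8 CPM with vehicle, SD, n = 5 each; log2 fold change -0.19, SE 0.06), and Gad2, a GABA-synthesising enzyme, had a log2 fold change of 0.18. Neither passed over all genes (edgeR adjusted p = 0.792 for both). Lhx5 (-0.18, and -0.10 without paclitaxel replicate 1) and Pvalb (-0.09, and -0.05 without vehicle replicate 3) followed. The medians of glutamate receptors and of dorsal horn neuropeptides with their receptors were -0.002 and -0.005 (camera adjusted p = 0.814 and 0.935), and excitatory dorsal horn neurons had a median of 0.05 (0.458).

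Inflammation and glial reaction genes did not pass in the main edgeR fit of all libraries. Medians were 0.11 for cytokines, chemokines and innate signalling (camera adjusted p = 0.814), 0.06 for interferon-stimulated genes (0.483), 0.01 for MHC and complement (0.814) and 0.08 for microglia (0.521). Without paclitaxel replicate 3 the microglia (0.15, 0.00433, from 8.28e-04 to 0.952 over all settings) and interferon lists (0.15, 0.0219, from 0.0024 to 0.973) were called higher. With all libraries and 1 surrogate variable, microglia (0.14, 8.28e-04) and interferon-stimulated genes (0.14, 0.0024) were called higher too. That variable mostly marked paclitaxel replicate 3 (-0.92, against -0.07 to 0.21 in the other libraries), so this is not separate support. Reactive astrocyte genes had a median of -0.03 (0.627). In that list Nes, the intermediate filament nestin, was at 15.4 ± 2.48 CPM with paclitaxel and 35.5 ± 16.2 CPM with vehicle (SD, n = 5 each; log2 fold change -1.19, SE 0.33; edgeR adjusted p = 0.792), and no overlap between the groups was seen. Hspb1 (-0.24, and -0.12 without vehicle replicate 4), Tm4sf1 (-0.25, and -0.13 without paclitaxel replicate 3) and Cp (0.27) followed. Cp ran from 0.12 without vehicle replicate 5 to 0.45 without vehicle replicate 4. Vehicle replicate 4 held 60.3 CPM of Nes, and the lowest vehicle library 21.2 CPM.

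Pathways linked to the drug's action gave medians of -0.06 for tubulins and microtubule proteins, -0.04 for the nuclear-encoded respiratory chain (camera adjusted p = 0.0975 for both), -0.03 for Nrf2 targets (0.627), -0.01 for p53 targets (0.622) and 0.12 for mitosis genes (0.432). The tubulin median was -0.016 without paclitaxel replicate 3 (0.96), whose score was -0.21, and the list was called without a low-count filter (0.0468) and without paclitaxel replicate 1 (0.0392), 4 (0.0411) or 5 (0.0418), with adjusted p from 0.0392 to 0.96 over all settings. The respiratory chain list had a median of -0.013 without paclitaxel replicate 1 (0.402) and, among other settings, was called without paclitaxel replicate 4 (0.0305) or 5 (0.0418) or vehicle replicate 4 (0.0332), with adjusted p from 0.0171 to 0.895 over all settings. The p53 target list was called lower without paclitaxel replicate 3 (-0.10, 0.0264, from 0.0168 to 0.967 over all settings). The circadian clock stood at 0.01 and cytosolic ribosomal proteins at -0.01 (0.814 and 0.992). The clock was called lower with 1 surrogate variable (-0.05, 0.0398, up to 0.987 over all settings) and ribosomal proteins higher after the GC and length correction (0.04, 0.00623, up to 0.998). The glucocorticoid response list had a median of 0.19 (0.209), and its direction turned without paclitaxel replicate 3 (median -0.14, camera adjusted p = 0.026, from 0.00246 to 0.903 over all settings). It was called higher without paclitaxel replicate 1 (0.27, 0.0392) or 4 (0.27, 0.0411) or vehicle replicate 5 (0.31, 0.0184). In paclitaxel replicate 3 Plin4, a lipid droplet protein, was at 160 CPM and the glucocorticoid-induced kinase Sgk1 at 411 CPM, against at most 57.7 and 172 CPM in the other libraries.

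**Figure D3:**
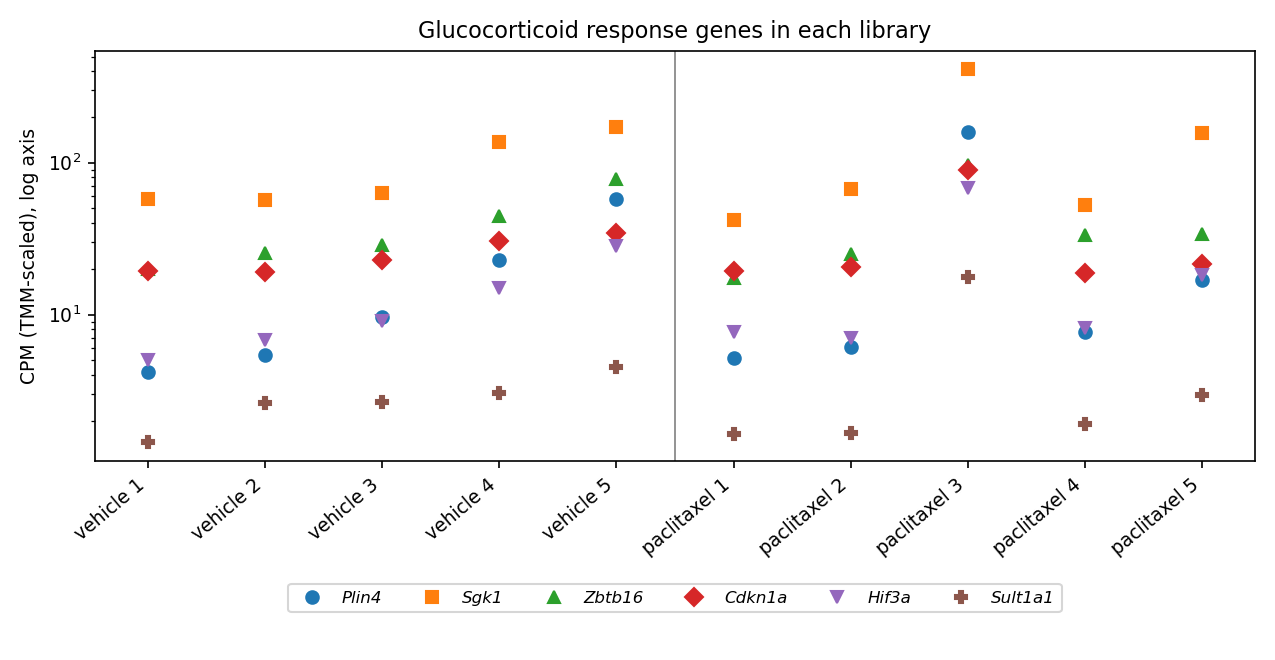
Level in CPM (vertical axis, log scale) of 6 genes of the glucocorticoid response list, Plin4, Sgk1, Zbtb16, Cdkn1a, Hif3a and Sult1a1, in each of the 5 vehicle and 5 paclitaxel libraries (horizontal axis); each marker is a gene in a single library. All 6 genes are highest in paclitaxel replicate 3, and vehicle replicate 5 holds the next highest levels, such as 57.7 CPM of Plin4.

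Markers of the cell types of the cord did not pass in the main edgeR fit of all libraries. Medians were -0.04 for neurons, -0.06 for motor neurons, 0.03 for astrocytes, 0.01 for myelinating oligodendrocytes, 0.02 for their precursors, -0.04 for endothelial cells, -0.11 for pericytes and smooth muscle and 0.03 for ependymal cells, with camera adjusted p between 0.0975 and 0.935. Pericytes and smooth muscle had a median of 0.009 without paclitaxel replicate 3 (0.808) and -0.06 without vehicle replicate 4 (0.183), and the list was called lower without a low-count filter (-0.13, 0.0386) and without paclitaxel replicate 2 (-0.15, 0.036), 4 (-0.15, 0.0411) or 5 (-0.20, 0.0218) or vehicle replicate 5 (-0.17, 0.0184), with adjusted p from 0.0184 to 0.959 over all settings. Without paclitaxel replicate 3 myelinating oligodendrocytes (0.06, 0.00388, from 0.0024 to 0.999 over all settings) and their precursors (0.09, 0.00433, from 0.00433 to 0.895) were called higher. With all libraries, 1 surrogate variable, which mostly marked paclitaxel replicate 3, called both higher (0.0024 and 0.00848). Limma-voom with sample quality weights called the precursors higher (0.0407). Tissue that dissection can add gave -0.27 for meninges and fibroblasts (0.0975), a value that rests on vehicle replicate 4, without which it was 0.009 (0.999), while the list was called without a low-count filter (-0.52, 0.00636), with a filter of at least 1 CPM in 5 libraries (-0.46, 0.00917), without paclitaxel replicate 1 (-0.34, 0.0476) and without vehicle replicate 1 (-0.36, 0.0233) or 3 (-0.34, 0.00777), with adjusted p from 0.00636 to 0.999 over all settings. The other medians were 0.03 for Schwann cells (0.814), -0.11 for sensory ganglion neurons (0.204) and -0.01 for erythroid cells (0.949). The median, the mean and the test differed in sign for 8 lists, all with adjusted p of 0.622 or more: CGRP signalling, neuropeptides, glutamate receptors, p53 targets, the clock, ependymal cells, erythroid cells and ribosomal proteins. Lists with fewer than 5 tested genes were not tested. Of 18 neutrophil and lymphocyte genes, 16 had counts listed and 0 were tested. Mitochondrially encoded mRNAs were not among the listed genes, so their level cannot be read here. Skeletal muscle had 1 tested member (Pvalb, also a neuronal gene), and sex-linked genes had 4, led by the Y-linked Ddx3y (log2 fold change 0.23, edgeR adjusted p = 0.792).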

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

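The tests of vehicle replicate 4 alone, of tissue handling, of endothelial cells and of the splits for the count of changed genes and for the lowest p of any list were chosen only after the result was seen. The unfolded protein response list was set apart from the heat shock and immediate early lists only after its call was seen to end without vehicle replicate 4. A library far from the others of its group was sought in 210 groups of 5 values, of which 21 stood out, where chance gives about 1 in 20, or 10.5. Of these, 13 were in paclitaxel replicate 3 and 4 in vehicle replicate 4. The groups included genes named after their values were seen, such as Cdkn1a, Sult1a1 and Hspa1b. The figure for chance therefore does not hold for this set.

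Glucocorticoid response genes were high in paclitaxel replicate 3, whose list score was 1.32 against -0.34 to 0.13 in the other paclitaxel libraries. Plin4, a lipid droplet protein, reached 160 CPM against 5.16 to 16.9 CPM in those 4 libraries, Sgk1, a glucocorticoid-induced kinase, 411 CPM against 41.7 to 156 CPM, Cdkn1a 89.8 CPM against 18.8 to 21.7 CPM and Sult1a1 17.6 CPM against 1.64 to 2.94 CPM. Fat in the sample is argued against, since 7 adipocyte genes (Adipoq, Plin1, Cidec, Cfd, Lep, Retn and Car3) together held 2.12 CPM beside a Plin4 excess of 151 CPM. With Fabp4 and Scd1, 2 more genes of that test, the sum was 709 CPM, above the bound set for fat, but nearly all of it was Scd1, at 706 CPM here and 656 to 814 CPM in the other libraries, so that bound was wrong for cord; Fabp4 had 0 CPM in this library. A trend with GC content or transcript length is argued against too, since the median log2 deviation of Plin4, Sgk1, Zbtb16, Cdkn1a, Hif3a and Sult1a1 was 2.67 before and 2.69 after the correction. A hormonal or stress state of that sample may account for the pattern and stays open, and no biological explanation was tested because the labels name none.

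The other values of paclitaxel replicate 3 that stood apart were scores of -0.21 for tubulins and microtubule proteins (others -0.005 to 0.008), -0.37 for motor neurons (0.002 to 0.08), -0.31 for myelinating oligodendrocytes (0.03 to 0.09) and 0.22 for p53 targets, a list that holds Cdkn1a (-0.13 to -0.06). Its gene levels that stood apart were 322 CPM for Erbb2ip (others 237 to 253), 19.1 CPM for Fam19a1 (12.5 to 13.6), 9.34 CPM for Serpinh1 (14.8 to 17.2), 1442 CPM for Hsp90ab1 (1665 to 1706), 4.46 CPM for Calcb (8.19 to 10.1) and 21.7 CPM for Hspb1 (30.0 to 32.8).

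The heat shock and immediate early lists were lower with paclitaxel, and vehicle replicate 4 stood apart in the score of the heat shock list (0.27 against -0.15 to -0.03 in the other vehicle libraries), Hspa1b (54.9 against 7.05 to 12.1 CPM), Klf4 (20.4 against 7.23 to 8.73 CPM) and the score of the meninges and fibroblasts (0.90 against -0.38 to -0.06). That library alone is argued against for the heat shock list, whose median was -0.10 without it, but stays open for the unfolded protein response list, whose median moved to -0.050 while its call ended. Leaving out paclitaxel replicate 3 moved that median further, to -0.034, and the call stayed. A trend with GC content or length is argued against, since the heat shock median was -0.15 after the correction. Of 100 splits of the 10 libraries drawn with the real one, 2 gave a camera p for the heat shock list as small as the real 2.55e-10 (the other 4.62e-11). For that list taken alone so small a p was rare among the splits, which does not exclude chance. With allowance for its choice as the lowest of 37, 23 of the 100 splits gave some list a camera p as small (lowest 6.12e-19), so chance cannot be excluded. Tissue handling or time to freezing that differed between the groups may also lower these genes. It predicts an immediate early median below 0, as measured (-0.194), but that test was chosen after the list was seen to be lower and decides nothing. Handling cannot be told apart from the drug, because the labels record no handling times.

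Calcrl was higher with paclitaxel at an unadjusted p only. More endothelial cells, which express Calcrl, are argued against as the whole source, since the endothelial list had a median of -0.0415, below the 0.46 of Calcrl by more than the SD of its members (0.18). The endothelial score was -0.48 in paclitaxel replicate 3, against -0.05 to 0.28 in the other paclitaxel libraries. Over all settings the endothelial median ran from -0.13 to 0.12, and the list's direction differed in 5 of 23. Calcrl was at 0.33 or above in all settings. A trend with GC content or length is argued against as the whole source, since the log2 fold change was 0.36 (SE 0.13) after the correction and 0.46 (SE 0.14) before. An effect of paclitaxel on Calcrl and chance among 13287 genes may each account for it and stay open; leaving out paclitaxel replicate 3 and vehicle replicate 4 gave 0.33.

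In single libraries, Pagr1a stood at 45.6 CPM in vehicle replicate 1 (others 53.6 to 54.7), the score of oligodendrocyte precursors at 0.087 in vehicle replicate 1 (-0.03 to -0.01), that of Nrf2 targets at 0.0255 in paclitaxel replicate 1 (-0.04 to -0.03) and that of endothelial cells at -0.20 in vehicle replicate 5 (0.02 to 0.08).

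Other splits of the libraries bear on the counts. The real one gave 0 changed genes, a count that all 100 splits reach by necessity, so this comparison decides nothing; the highest of the others gave 22. For genes at an unadjusted p under 0.05, 18 splits gave at least the real 806, up to 1891 with a median of 524.5, and chance cannot be excluded. For lists past an adjusted p of 0.05 in camera, 67 splits gave at least the real 5, up to 18, and chance cannot be excluded. The 22 genes and 18 lists are the highest of many splits, so setting them against 1 real split cannot show a structure of the samples other than treatment. Over the 100 splits the median was 0 genes and 7 lists.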

How the results depend on the processing

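The settings that left out paclitaxel replicate 3 and vehicle replicate 4 together, corrected for GC content and length, thinned the counts or removed Hspa1a and Hspa1b were chosen after seeing the data. The count of changed genes was 0 under the scaling, filter and leave-one-out settings (0 to 0), with 1 gene lower in DESeq2, 1 in edgeR's likelihood ratio test and 2 in its exact test, and with 806 at an unadjusted p under 0.05; the cause was not tested. Genes at an unadjusted p ranged from 508 (both libraries left out) to 1299.

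The labels do not say whether equal replicate numbers share a litter or day, and the counts do not settle it. Correlations of same-numbered deviations ran from -0.10 to 0.14, and those of other numbers from -0.18 to 0.12. Of the same-numbered ones 2 of 5 were above 0.1, and 2 of 5 paclitaxel libraries matched their own number best. With the replicate number as a block 1 gene was called, Fos, lower, and the cause was not tested.

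Calcrl kept its direction and an unadjusted p under 0.05 in all 25 settings (0.33 to 0.59; without each library 0.39 to 0.59), with adjusted p from 0.363 to 1.00. Kmt2d (-0.08 to 0.05) and Kmt2b (-0.04 to 0.05) changed sign in 14 and 6 settings and passed in 0. The 20 genes of lowest p kept their direction in all 499 values, and 3 passed, all Klf4 (adjusted p from 0.00152 to 1.00). They were chosen for low p in these same counts, so a kept direction is not independent evidence. Sizes moved more: the lowest values over all settings included 0.08 for Cfl2, 0.16 for Gabrg1 and 0.16 for Vma21.

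The number of lists called, 5, was 3 to 9 when each library was left out, 10 without a low-count filter, 12 with 1 surrogate variable, 9 without paclitaxel replicate 3 and vehicle replicate 4, and 0 with an estimated correlation; the cause was not tested. The number was 9 without paclitaxel replicate 3 or 4, 8 without paclitaxel replicate 5 and 3 without vehicle replicate 2. Of 116 values of the 5 called lists, 96 stayed called and 20 did not, 0 with another direction. Of 736 values of the other 32, 39 passed in the same direction and 4 reversed: the glucocorticoid list was called lower with 1 surrogate variable (median -0.137), without paclitaxel replicate 3 (-0.138) and without both libraries (-0.124), while it was called higher without paclitaxel replicate 1 (0.269) or 4 (0.271) or vehicle replicate 5 (0.314), and ribosomal proteins were called higher after the GC and length correction (0.038). Where camera was run, the heat shock list was called in 23 of 24 alternatives, all but the estimated correlation; fry, run with all libraries, did not call it (adjusted p = 0.469). Simulated data of this depth and spread held 200 changed genes per set. There 19.3% of genes changed 1.2-fold and 91.8% of those changed 2-fold were recovered, so depth and spread limit small changes. The adjustment is stricter where fewer genes change, so these rates need not hold for the real comparison.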

Other observations

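Genes of low p that were higher and lower with paclitaxel had different median GC contents. The 391 genes higher with paclitaxel at an unadjusted p under 0.05 had a median GC content of 43.7% and a median transcript length of 4215 bases, the 415 lower genes 56.4% and 2574 bases, and all tested genes 50.4% and 3188 bases. After the correction for GC content and length, 196 of the higher and 210 of the lower genes still had an unadjusted p under 0.05. Among all tested genes 596 had such a p after the correction, where 664 would be reached by chance. The slope of a library's log2 deviation on GC content, per 10 percentage points, was -0.04 ± 0.07 with paclitaxel and 0.04 ± 0.08 with vehicle (SD, n = 5 each; exact permutation test, two-sided, p = 0.127). Libraries of both groups lay at the AT-rich end, with slopes of -0.15 in paclitaxel replicate 3 and -0.10 in vehicle replicate 1. Slopes were negative in all paclitaxel libraries except replicate 2 (0.03) and positive in all vehicle libraries except replicate 1.

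Glucocorticoid response genes also varied among the vehicle libraries. Vehicle replicate 5 had a list score of 0.57, with 57.7 CPM of Plin4, 172 CPM of Sgk1, 78.4 CPM of Zbtb16 and 28.2 CPM of Hif3a, against 4.16 CPM, 58.0 CPM, 19.9 CPM and 5.06 CPM in vehicle replicate 1. The first principal component of the 10 libraries held 22.4% of the variance and set paclitaxel replicate 3 (35.4) apart from the others (-9.10 to -0.12).

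Without paclitaxel replicate 3, lists of glia and of interferon signalling, none of which passed in the main edgeR fit of all libraries, were called higher with paclitaxel: microglia (median 0.15, camera adjusted p = 0.00433, from 8.28e-04 to 0.952 over all settings), interferon-stimulated genes (0.15, 0.0219, from 0.0024 to 0.973), myelinating oligodendrocytes (0.06, 0.00388, from 0.0024 to 0.999) and oligodendrocyte precursors (0.09, 0.00433, from 0.00433 to 0.895). The p53 target list was called lower (-0.10, 0.0264, from 0.0168 to 0.967). These calls used the preset correlation of 0.01 and were not run with an estimated correlation without that library. With all libraries and 1 surrogate variable these lists were called in the same directions. That variable mostly marked paclitaxel replicate 3 (-0.92, against -0.07 to 0.21 in the other libraries). The setting thus nearly repeats leaving that library out and is not separate support. Oligodendrocyte precursors were also called higher with all libraries in limma-voom with sample quality weights (camera adjusted p = 0.0407).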
